A study of Sus scrofa with 17 samples.

How the data were processed

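The samples were longissimus dorsi muscle of Luchuan pigs at E35 and E80, with 3 Hi-C and 3 RNA-seq libraries per stage, H3K27ac ChIP-seq with 2 libraries at E35 and 1 at E80, and 1 input per stage. Per the labels, Hi-C was made in situ with DpnII after fixation with 4% formaldehyde, RNA was depleted of ribosomal RNA and read as stranded pairs of 150 bp, and chromatin for ChIP was sheared to between 200 and 500 bp. The labels give a different antibody code for each of the 3 H3K27ac libraries. The submitters' processing notes name BWA 0.7.15, Juicer, STAR 2.6.0c, Cufflinks 2.1.1, kallisto 0.44.0, MACS2 and SAMtools 1.3.1 with the build Sscrofa11.1, and mostly give neither the role nor the order of the tools. All work started from the deposited tables, and no reads were aligned.

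The authors deposited expression as TPM, a transcript abundance scaled to a fixed total, for 22342 gene identifiers. The columns summed to less than that total, so part of each library lay in features that are not in the table, and 3449 identifiers were at 0 in all libraries. The authors deposited the A/B index as a score per bin of 20 kb, above and below 0, without stating its formula or scale. The D-score was deposited by the authors as a fraction between 0 and 1 for each of 3654 consensus TADs, with no formula. TAD positions in bp were deposited by the authors per library, per stage and as a consensus, in other units than a signal. The bin tables and the consensus hold 18 autosomes and no X chromosome. Per the file headers, each H3K27ac region list gives the read counts of the ChIP library and of the input in each region, with no normalization. Per the file headers it also gives the fold change, a ratio of ChIP to input reads that was found to be scaled by the library totals. A p-value and an FDR per region were deposited by the authors from the peak caller. The lists carry the name of SICER and of removed duplicates, while the processing notes name MACS2, and they were not filtered, since they hold regions with an FDR up to 1. TPM, index and D-score keep no depth, so their counting error is unknown. For H3K27ac the ChIP reads in regions numbered between 20740103 and 29481731 per library, counting error only.

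Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, R 4.3.3 with limma 3.58.1, and bedtools 2.31.1. The comparisons, the gene lists, the anchor genes, the rule for naming genes and the alternatives were fixed before the data were examined. Samples were grouped by stage as labelled, and the labels do not say whether libraries with the same number came from 1 animal or whether replicates came from separate animals.

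Expression was compared as log2(TPM + 1) for genes with a mean of at least 1 TPM, 14353 in number, with limma, a variance trend and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. Index and D-score were compared with limma without a variance trend, per bin and per TAD. A bin was called switched where the sign of the stage mean differed and its adjusted p was under 0.05, and neighbouring switched bins were joined into runs. TAD number, length and shared edges were compared by exact permutation over the 10 splits of 6 libraries into 3 and 3, which cannot give a two-sided p under 0.1. Edges were called shared within 40 kb.

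The 24 gene lists covered myogenic regulators, sarcomere, myosin heavy chains, calcium handling, neuromuscular junction, glycolysis, oxidative phosphorylation, fatty acids, cell cycle, matrix, HOX and patterning, heterochronic and growth factors, Notch and Wnt, chromatin architecture, fibre type regulators, and markers of neurons, Schwann cells, endothelium, erythroid cells, leukocytes, cartilage, epithelium, adipocytes and tendon. They were tested with camera of limma at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry. Genes were named by a fixed rule: the anchor genes, the 5 highest and 5 lowest log2 changes among genes with a symbol, an adjusted p under 0.05, a mean of at least 10 TPM and stages that did not overlap. In each list the 2 members with the largest absolute change were named. The 3 longest switched runs each way, the 3 TADs with the largest rise and fall past the test and the 3 longest H3K27ac regions of each stage alone were named too.

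Gene positions came from RefSeq on Sscrofa11.1 for the 13477 symbols with 1 position, and 10824 tested genes were placed, 10440 of them on autosomes. The position table gives no strand, so transcription starts were unknown. Genes were placed in bins and TADs by the middle of the gene body, and H3K27ac was taken at a gene when a region lay within 2 kb of either gene end. E35 regions were the merged regions found in both libraries, and an overlap of 1 bp counted. H3K27ac was read on chromosomes 1 to 18 and X, and regions on unplaced scaffolds were left out. Expression changes were compared between classes of genes as differences of medians, with p-values from 10000 circular shifts of the values along the gene order, whose smallest p is 0.0001, and adjusted over 11 tests. Alternatives used 1000 shifts.

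Alternatives were a pseudocount of 0.1 TPM, no filter or a minimum of 5 TPM, median-of-ratios and quantile scaling, an absolute log2 change of at least 1, a variance per group, the replicate number as a block, and each library left out in turn. For Hi-C they were quantile normalization, centring on the library median, a variance trend, a logit of the D-score, TADs of at least 200 kb, other rules for switching, and edges shared at the same position or within 20 or 80 kb. For H3K27ac they were an FDR of at most 1e-10, an overlap of 50% of the region, E35 regions of either library, lists of the same number of regions ranked by fold, and gene ends within 5 kb. After the data had been seen, TPM rescaled without the 2 leading genes of E80 replicate 2, regions with an FDR of at most 0.01 and a fold over 1, the quantile-normalized index in the comparison of expression by compartment, median-of-ratios scaling in that by D-score, and each E35 H3K27ac library left out were added.

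The methods were tested on simulated data with the spread of these libraries. Each simulation changed 100 of 14353 genes, 113298 bins or 3654 TADs. Far more features passed in the data, where the adjusted cut was therefore less strict, so the shares below do not measure its power. For expression, a log2 change of 1 was recovered for 45% of changed genes and of 2 for 88%, with 1.5% false calls. For the index, changes of 1 and 2 were recovered for 3% and 57% of bins. For the D-score, changes of 0.02 and 0.04 were recovered for 88% and 97% of TADs, with 2.6% false calls. The shift test, simulated for expression in switched compartments alone, called 5% of 100 runs with no added change, and 100% with 0.1 added. Small classes had wider ranges over the shifts, -0.127 to 0.124 for genes with H3K27ac at E80 alone, so 0.1 would not pass there.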

Results

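Longissimus dorsi, the long muscle of the back, was sampled from Luchuan pigs, a Chinese breed, at embryonic day 35 (E35) and embryonic day 80 (E80), and the labels give female for every sample. In pigs the primary muscle fibres begin to form around the earlier stage and the secondary fibres form around the later one. The series title names the reorganization of chromatin architecture over this time as its subject, so each comparison asks how E80 differed from E35. The 17 samples comprised 3 in situ Hi-C libraries per stage, which read contacts between parts of the genome, and 3 RNA-seq libraries per stage. The others were ChIP-seq of H3K27ac, a histone acetylation found at active promoters and enhancers, with 2 libraries at E35, 1 at E80 and 1 input per stage. The expression table gave TPM, a transcript abundance scaled to a fixed total per library, for 22342 Ensembl gene identifiers, of which 14749 carried a symbol, and its columns summed to between 783345 and 840426. The Hi-C tables gave an A/B index for 113298 bins of 20 kb, a D-score for 3654 consensus topologically associating domains (TADs), and TAD positions per library. The read depth behind the TPM, index and D-score values is unknown. The labels do not say that replicates came from separate animals. The limma p-values per gene, bin and TAD therefore measure the spread between these libraries, which may be technical. The p-values from shifts of the gene order compare classes of genes along the genome and measure no spread between libraries.

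Genes of fast muscle contraction were among the strongest gains at E80, and genes of neurons and of the embryonic mesenchyme among the strongest losses. ART3, which encodes an ADP-ribosyltransferase family member (ENSSSCG00000008976), rose from 0.485 ± 0.565 to 106 ± 33.3 TPM (mean and SD, n = 3 per stage), a log2 change of 6.19 ± 0.32 (SE). EGF, a growth factor, rose by 5.25, DUSP26, a phosphatase, by 5.07, and TMOD4, a tropomodulin of skeletal muscle that caps thin filaments, by 4.52. STMN2, a neuronal microtubule regulator (ENSSSCG00000006160), fell from 137 ± 27.1 to 0.884 ± 0.534 TPM, a log2 change of -6.21 ± 0.23. CPS1, the first enzyme of the urea cycle, had a change of -4.93, SFRP1, a secreted Wnt antagonist, of -4.56, CYTL1, a secreted protein of cartilage precursors, of -4.54, and COL8A1, a short-chain collagen, of -4.22. COL8A1 differed widely within E35 (132 ± 160 TPM, highest in replicate 3), and its call was lost without E80 replicate 2 (adjusted p = 0.0556) or E80 replicate 3 (adjusted p = 0.0503).

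Among 14353 genes with a mean of at least 1 TPM, 6615 (46.1%) passed the limma test, 1467 higher and 5148 lower at E80, and 2285 of them changed by at least 1 on the log2 scale. The values of the stages did not overlap for 8554 genes (59.6%, against 10% by chance). The split between higher and lower depended on scaling, because the median log2 change over all tested genes was -0.30. With median-of-ratios scaling the counts were 2542 higher and 2402 lower (51.4% higher, against 22.2% with TPM as deposited), and with quantile normalization they were 2473 and 2574 (49.0% higher). Of the 6615 genes, 3869 kept their call and sign under median-of-ratios scaling and 49 changed sign. Without E80 replicate 3 the genes called higher were 938.

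The anchor genes of muscle development, fixed before the data were examined, moved apart. MYH8, the perinatal myosin heavy chain, rose from 803 ± 282 to 4971 ± 687 TPM (log2 change 2.68 ± 0.28). MYH3, the embryonic myosin heavy chain, stood at 3230 ± 1396 and 2378 ± 344 TPM and did not pass the test (log2 change -0.36, adjusted p = 0.410). SLN, which encodes sarcolipin, a regulator of the calcium pump, rose by 3.69 ± 0.39. DLK1, an imprinted growth regulator, rose by 1.69, MEF2D, a myogenic transcription factor, by 1.03, and MATN2, a matrix protein, by 0.73. IGF2BP1, a fetal RNA-binding protein, fell from 76.1 ± 6.94 to 4.98 ± 0.840 TPM (log2 change -3.69 ± 0.14), and MUSK, the receptor kinase of the neuromuscular junction, fell from 65.8 ± 24.3 to 9.91 ± 2.01 TPM (-2.56 ± 0.29). NEFL, a neurofilament, had a log2 change of -3.15 ± 0.41. The myogenic regulators MYF5 (-0.68, adjusted p = 0.0692), MYOG (-0.47, adjusted p = 0.341), MYOD1 (0.44, adjusted p = 0.280) and PAX7 (0.16, adjusted p = 0.669) did not pass. Nor did the growth inhibitor MSTN (0.70, adjusted p = 0.271) and the adult acetylcholine receptor subunit CHRNE (0.33, adjusted p = 0.262). SOX6, a repressor of slow fibre genes, rose by 1.02 (adjusted p = 0.0228), but not without E35 replicate 2 (adjusted p = 0.0612), E80 replicate 1 (adjusted p = 0.0736) or E80 replicate 3 (adjusted p = 0.0751). MYF6 rose by 0.89 (adjusted p = 0.0433), and among the libraries left out 1 at a time its call held only without E35 replicate 1. Leaving out E35 replicate 2 or 3 gave adjusted p = 0.0768 and 0.0954, and leaving out E80 replicate 1, 2 or 3 gave adjusted p = 0.126, 0.0511 and 0.0919.

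**Figure D1:**
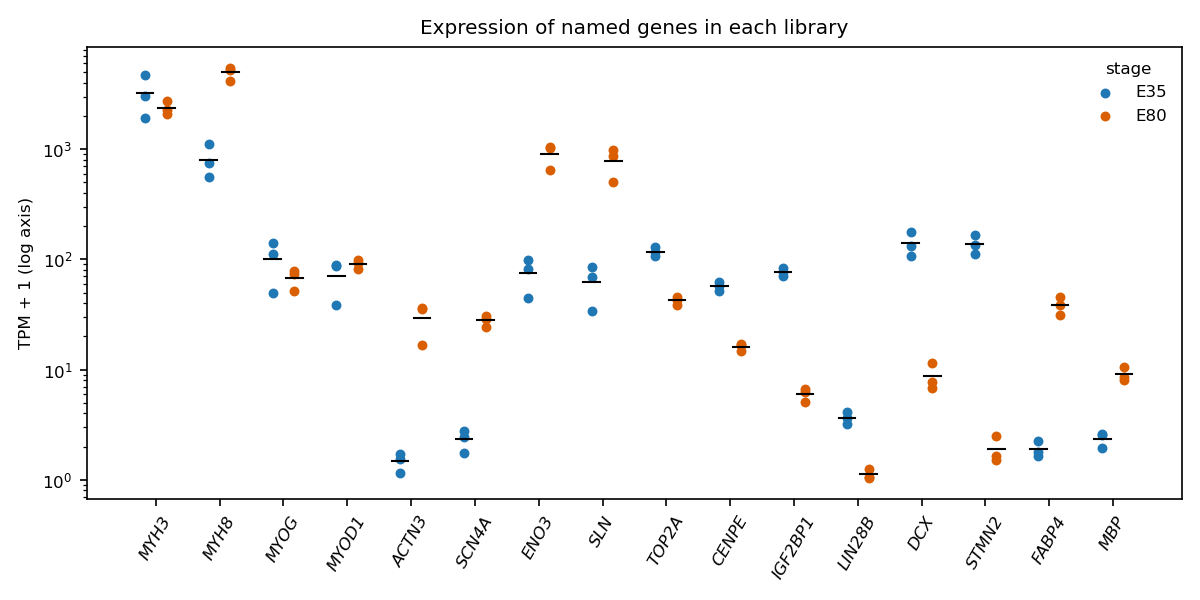
TPM + 1 of chosen genes of muscle, cell division, embryonic growth, neurons, fat and myelin, on a log axis, with 1 point per library (3 per stage) and bars for the stage means. MYH8 lay between 556 and 1110 TPM at E35 and between 4198 and 5511 TPM at E80.

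Most measured genes of the sarcomere and of calcium handling rose. Of 30 measured sarcomere genes 19 rose and 11 did not pass the test (22 higher and 1 lower adjusted over the list alone), with a list median of 1.35, which is 1.65 above the median of all genes. Without E35 replicate 3, 3 members fell. ACTN3, the alpha-actinin of fast fibres, rose from 0.465 ± 0.294 to 28.4 ± 10.9 TPM (log2 change 4.27), and MYOZ1, a Z-disc protein of fast fibres, rose by 4.14. The list passed camera, which ranks a list against all other genes (adjusted p = 5.96e-14), but not with a correlation estimated between its genes (adjusted p = 0.298 with an estimated correlation). Of 15 genes of calcium handling and excitation-contraction coupling 11 rose, SLN and SCN4A, the sodium channel of muscle (3.61), the most, and ASPH fell (-0.50), with the same counts adjusted over the list alone. ASPH did not pass under median-of-ratios scaling, nor without E35 replicate 2 or any 1 of the E80 replicates. That list had a median of 1.58 and adjusted p = 2.94e-10, or adjusted p = 0.298 with an estimated correlation. Among 5 skeletal myosin heavy chains in the table MYH8 rose and MYH7B fell (-0.93), also adjusted over the list alone, and MYH13, an extraocular myosin, went from 9.55 ± 7.40 to 31.6 ± 35.3 TPM without passing (adjusted p = 0.209), at 72.4 TPM in E80 replicate 2 against 10.3 and 12.2 TPM in the other E80 libraries. MYH7B passed neither under median-of-ratios scaling nor with any 1 library other than E35 replicate 3 left out, and 2 members rose without E35 replicate 1. The list did not pass (median 0.99, adjusted p = 0.0902), although it did without E35 replicate 1 (adjusted p = 0.0233). Of 17 fibre type regulators 7 rose, among them NR4A3, a nuclear receptor (1.32), and EYA1, a transcriptional coactivator, fell (-1.12), the same adjusted over the list alone. This list had a median of 0.39 and adjusted p = 4.53e-05, or adjusted p = 0.293 with an estimated correlation, and 11 members rose under median-of-ratios scaling. Without E35 replicate 3, 2 members fell.

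Of 18 myogenic regulators and progenitor factors DES, the muscle intermediate filament (2.11), MEF2D and MYF6 rose, EYA1 and TCF12 (-0.54) fell, and 13 did not pass (2 higher and 2 lower adjusted over the list alone). The members that fell were 5 without E35 replicate 3, 3 without E35 replicate 2, and 1 without E35 replicate 1 or any 1 of the E80 replicates, and neither EYA1 nor TCF12 passed under median-of-ratios or quantile scaling. EYA1 lost its call under median-of-ratios scaling (adjusted p = 0.0669) and without E35 replicate 1 (0.0654) or E80 replicate 1 (0.0604), 2 (0.0914) or 3 (0.0561). The median of the list was -0.04, its mean 0.07 and the direction of camera upward (adjusted p = 0.104), and it passed upward without E35 replicate 2 (adjusted p = 0.0339). Of 13 genes of the neuromuscular junction LAMB2, a laminin of the synaptic basal lamina, rose by 1.75, and MUSK, the receptor subunit CHRNA1 (-1.32), the organizer AGRN (-1.13) and UTRN (-0.40) fell, the same adjusted over the list alone. The members that fell were 2 without E35 replicate 2 or E80 replicate 1, 2 or 3, and under median-of-ratios scaling, and 6 without E35 replicate 3. Its median (-0.24) and mean (-0.31) were below 0 while camera, which ranks a list against all other genes, placed it upward. The median of all genes was -0.30, and the list did not pass (adjusted p = 0.712). E35 replicate 3 stood apart beside these muscle lists: it had the lowest value of its stage for DES (367, against 998 and 618 TPM), MYOZ1 (18.2, against 55.5 and 34.7 TPM) and MYH3 (1932, against 4707 and 3050 TPM). List members named beyond the 2 per list fixed in advance, here and for the lists that follow, were chosen after their values were seen.

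Most measured genes of glycogen and glycolysis rose. Of 21 measured genes 13 rose, ENO3, the muscle enolase, from 74.1 ± 28.2 to 906 ± 222 TPM (log2 change 3.64) and FBP2, the muscle fructose bisphosphatase, by 3.38. HK1, the hexokinase of many tissues, fell (-1.11), and the counts were the same adjusted over the list alone. The median was 0.97 and adjusted p = 2.94e-10, or adjusted p = 0.298 with an estimated correlation. Of 21 genes of fatty acid uptake and oxidation 9 rose, CPT1B, which carries fatty acids into muscle mitochondria, by 1.98 and PPARA, a nuclear receptor, by 1.65 (9 higher and 1 lower adjusted over the list alone). The median was 0.42 and adjusted p = 5.63e-07, or adjusted p = 0.298 with an estimated correlation. Under median-of-ratios scaling 14 of them rose. Of 30 genes of oxidative phosphorylation and the citrate cycle 4 rose, among them COX7A1, the muscle form of a cytochrome oxidase subunit (1.28), NDUFA4 (0.93) and SDHA (0.50). COX8A fell (-0.85), 25 did not pass, and 1 was higher adjusted over the list alone. Without E35 replicate 2 or 3 or E80 replicate 1 or 3 the members that rose were 2. The median was 0.16 and adjusted p = 4.53e-05, or adjusted p = 0.590 with an estimated correlation, and 15 members rose under median-of-ratios scaling. NDUFA4 lost its call without E35 replicate 2 (adjusted p = 0.0825) or 3 (0.0723), or without E80 replicate 1 (0.0760), 2 (0.0551) or 3 (0.107), with the replicate number as a block (0.0708), and without a filter on low values (0.0504).

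Cell division genes fell together. All 29 measured cell cycle genes fell with TPM as deposited, also adjusted over the list alone, and 25 did under median-of-ratios or quantile scaling. The median was -1.22, which is -0.92 relative to the median of all genes. CENPE, a kinetochore motor, fell from 56.1 ± 5.46 to 15.2 ± 1.32 TPM (log2 change -1.82), and KIF20A, a motor of cytokinesis, had a change of -1.67. The list had adjusted p = 2.94e-10, or adjusted p = 0.293 with an estimated correlation. Of 33 genes of chromatin architecture and the nuclear lamina 24 fell (25 adjusted over the list alone). CBX5, the heterochromatin protein HP1 alpha, fell from 148 ± 2.79 to 55.6 ± 2.50 TPM (-1.40), and SMC2, a condensin subunit, had a change of -1.23. That list had a median of -0.53 and adjusted p = 0.000189, or adjusted p = 0.301 with an estimated correlation, and under median-of-ratios scaling 13 members fell and 2 rose.

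**Figure D2:**
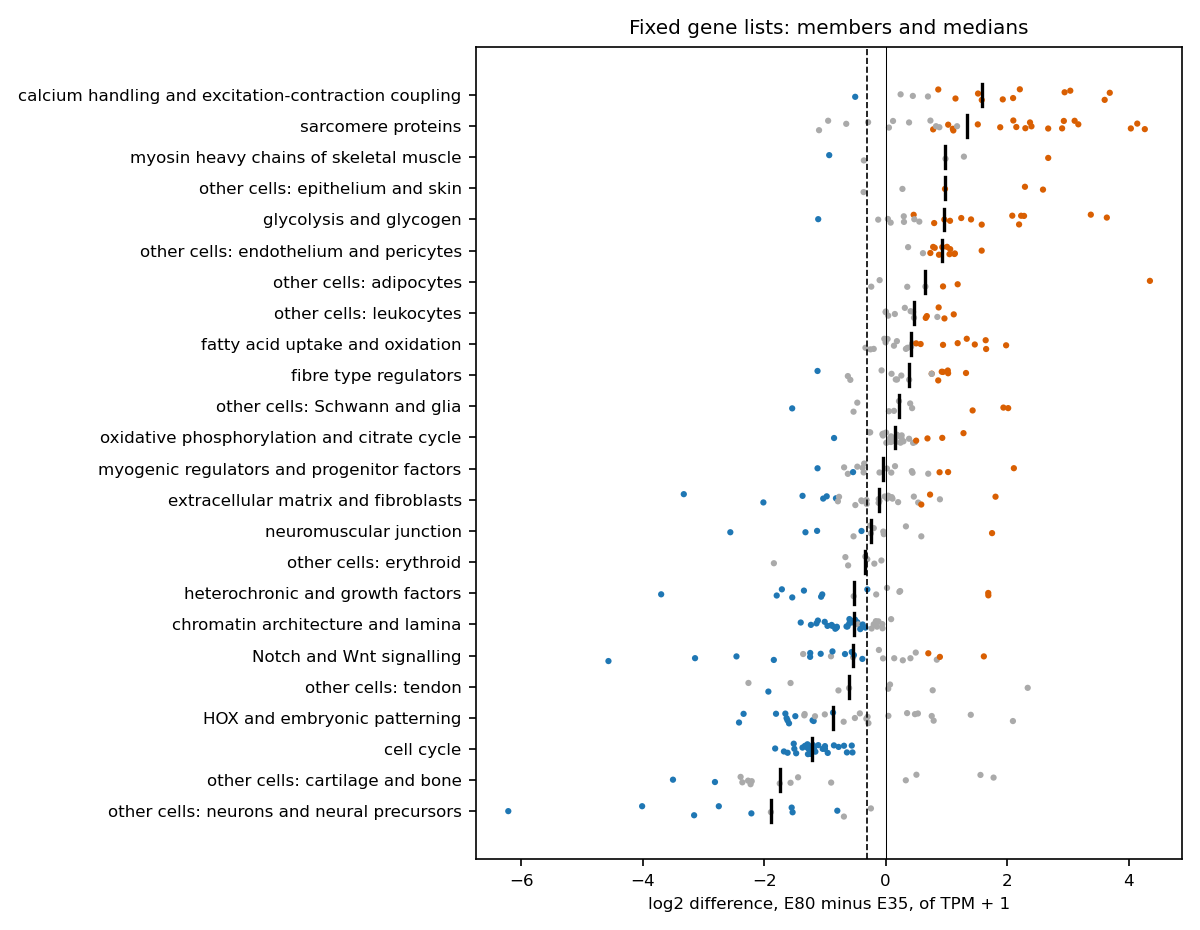
Log2 change from E35 to E80 of each measured member of the fixed gene lists, 1 point per gene. Orange points were higher at E80 and blue points lower past the test, grey points did not pass, black bars are list medians, and the dashed line is the median of all genes (-0.30). The cell cycle list lay below that line and the sarcomere, calcium handling and glycolysis lists mostly above it.

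Growth and patterning genes of the embryo changed in mixed ways. Of 15 heterochronic and growth factors 8 fell, with IGF2BP1 and IGFBP2 (-1.79), which binds insulin-like growth factors, the most, and DLK1 and LIN28A (1.69) rose, while LIN28B, the paralog of LIN28A and like it a repressor of let-7, fell (-1.71). The counts were the same adjusted over the list alone, and the list did not pass (median -0.53, adjusted p = 0.575). Of 25 Notch and Wnt genes 12 fell, SFRP1 and WNT5A, a Wnt ligand (-3.14), the most, and JAG2 (1.62), DLL4 (0.89) and NOTCH1 (0.70) rose (14 lower and 5 higher adjusted over the list alone). That list did not pass (median -0.53, adjusted p = 0.889), and under median-of-ratios scaling 8 fell and 6 rose. Without E80 replicate 1 or 3 the members that fell were 8, and without E35 replicate 1 those that rose were 5. Of 29 HOX and patterning genes 11 fell and 18 did not pass (10 lower adjusted over the list alone), with ZIC1, a zinc finger factor of the dorsal somite, falling from 48.3 ± 27.1 to 7.41 ± 0.542 TPM (-2.41). HOXA2 had a change of -2.34 (adjusted p = 0.0444), and its call was lost under median-of-ratios scaling (0.0756) and without E35 replicate 1 (0.116), E35 replicate 3 (0.118) or E80 replicate 1, 2 or 3 (0.0955, 0.127 and 0.109). The HOX list did not pass (median -0.87, adjusted p = 0.614), but did under median-of-ratios scaling (adjusted p = 0.0411) and without E35 replicate 1 (adjusted p = 0.0110). It had 7 members that fell without E80 replicate 1, and 3 that rose without E35 replicate 2.

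The E35 libraries stood apart from each other in their HOX genes, which set position along the body axis, replicates 1 and 2 in opposite ways. HOXA9 was at 0.141, 58.4 and 31.3 TPM in E35 replicates 1, 2 and 3, and HOXA10 at 0, 44.2 and 3.47 TPM, against 31.2 to 34.5 TPM of HOXA9 and 16.6 to 37.2 TPM of HOXA10 at E80. All 11 measured genes of paralog groups 7 to 10 were lowest in E35 replicate 1 among the libraries of its stage, and 4 of 6 genes of groups 1 to 3 were highest there. In E35 replicate 2 7 of the 11 posterior genes were highest, and the anterior genes HOXA2 (1.97, against 27.2 and 18.6 TPM) and HOXB3 (3.36, against 25.4 and 22.4 TPM) were lowest.

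**Figure D3:**
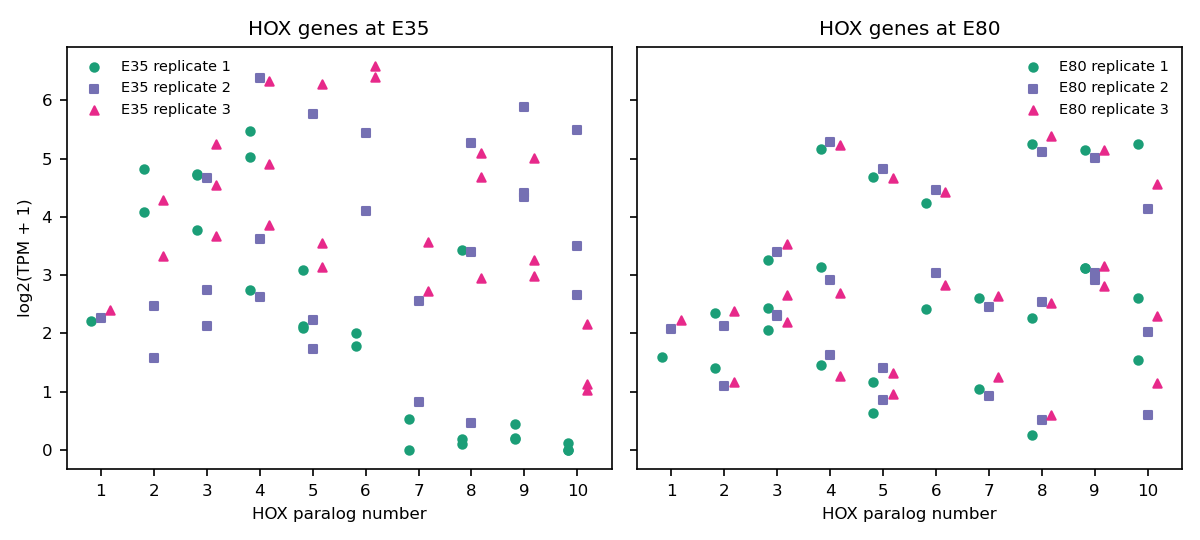
Log2(TPM + 1) of 25 HOX genes against their paralog number, from anterior to posterior, with 1 kind of point per library, for both stages. At E35 replicate 1 was lowest for the 11 genes of groups 7 to 10, while the E80 libraries lay close together.

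Markers of other cell types that a dissected muscle could hold also differed. Of 11 measured neuronal markers 8 fell (9 adjusted over the list alone), STMN2 and DCX, a microtubule protein of migrating neurons (138 ± 36.0 to 7.69 ± 2.48 TPM, log2 change -4.01), the most. The list had a median of -1.89 and adjusted p = 0.00352, or adjusted p = 0.293 with an estimated correlation. Of 11 Schwann cell and glial markers 3 rose, among them MBP, a myelin gene (1.94), and the crest factor FOXD3 (1.43), and NGFR, the neurotrophin receptor of immature Schwann cells, fell (-1.54), the same adjusted over the list alone. That list passed upward (median 0.22, adjusted p = 0.00495, or adjusted p = 0.506 with an estimated correlation), but not without E35 replicate 3 (adjusted p = 0.0611) or among genes of at least 5 TPM (0.102). Without E35 replicate 1 the markers that rose were 5, and without E35 replicate 3 those that fell were 2. Of 13 endothelial and pericyte markers 11 rose, also adjusted over the list alone, with RGS5, a pericyte marker (1.58), and TEK, the angiopoietin receptor (1.14), the most. Its median was 0.93 and adjusted p = 1.67e-09, or adjusted p = 0.298 with an estimated correlation. Of 14 leukocyte markers PTPRC (1.12), CSF1R (0.97), CD163 (0.87), TYROBP (0.68) and C1QA (0.66) rose (4 adjusted over the list alone), with a median of 0.46 and adjusted p = 1.51e-05, or adjusted p = 0.293 with an estimated correlation. Between 2 and 6 leukocyte markers rose when 1 library was left out, 2 of them without E35 replicate 2 or E80 replicate 3, and 9 rose under median-of-ratios scaling. Of 7 adipocyte markers FABP4, a fatty acid binding protein (0.891 ± 0.300 to 37.7 ± 7.20 TPM, 4.35), LPL (1.19) and PNPLA2 (0.95) rose, also adjusted over the list alone. The list had a median of 0.66 and adjusted p = 0.000775, or adjusted p = 0.293 with an estimated correlation. LPL lost its call without E80 replicate 1 (adjusted p just over 0.05) or 3 (adjusted p = 0.0531). Of 5 epithelial markers CDH1 (2.59), CLDN7 (2.29) and TP63 (0.98) rose, also adjusted over the list alone. The list had adjusted p = 0.00276, or adjusted p = 0.298 with an estimated correlation. It did not pass among all genes with a value above 0 (adjusted p = 0.0640) or among genes of at least 5 TPM (0.110).

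Skeletal connective tissue did not pass as groups. Of 28 matrix and fibroblast genes 6 fell, TNC, a matrix protein of developing tendon and muscle (304 ± 159 to 26.8 ± 2.49 TPM, -3.32), and FBN2, a fibrillin of the embryo (-2.01), the most. COL15A1 (1.81), MATN2 and COL4A2 (0.59) rose, with the same counts adjusted over the list alone. Without E35 replicate 3, 5 members rose. Its median (-0.11) and mean (-0.28) were below 0 and the direction of camera upward (adjusted p = 0.335). Of 15 cartilage and bone markers COL9A1 (-3.50) and MATN3 (-2.81) fell, 1 of them adjusted over the list alone, with a median of -1.74 and adjusted p = 0.889. COL9A1 lost its call under median-of-ratios scaling (adjusted p = 0.0576) and without E35 replicate 2 (0.0692) or E80 replicate 1, 2 or 3 (0.0927, 0.0882 and 0.0915). Of the cartilage markers 6 fell and 2 rose without E35 replicate 3, 5 fell without E35 replicate 1, and 1 fell without E80 replicate 1, 2 or 3. Of 9 tendon markers SCX, a tendon transcription factor, fell (-1.93), also adjusted over the list alone, and 3 fell without E35 replicate 1 and 2 without E35 replicate 2, while 1 rose without E80 replicate 3. COMP, at 0 in all E35 libraries and 7.31 ± 9.28 TPM at E80 (adjusted p = 0.0528), and TNMD, at 561 ± 376 and 109 ± 83.5 TPM (adjusted p = 0.0547), did not pass, and E80 replicate 2 stood apart for COMP at 17.9 TPM. The tendon list had a median of -0.60 and a mean of -0.43 with camera upward (adjusted p = 0.712), and downward under median-of-ratios scaling. Of 7 erythroid genes 0 passed by limma (1 at an unadjusted p under 0.05, and 0 adjusted over the list alone). HBZ was at 14.4 ± 13.1 and 3.01 ± 2.84 TPM and HBM at 8.89 ± 1.56 and 5.54 ± 2.71 TPM. The list had a median of -0.33 and adjusted p = 0.889. E35 replicate 3 was highest of its stage for the cartilage collagen COL2A1 (503, against 42.0 and 99.6 TPM), for TNC (474, against 279 and 159 TPM) and for HBZ (29.5, against 5.43 and 8.36 TPM).

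In all, 14 of the 24 lists passed camera, 11 upward and 3 downward, and 0 passed with an estimated correlation (3 at an unadjusted p under 0.05). The directional test of fry, which asks whether the genes of a list move 1 way and does not compare it with other genes, passed for 14 lists, 12 of them among those of camera, and its mixed test for 20.

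The bins of single anchor genes changed the sign of their index, toward the A state, in which active genes lie, or away from it. The libraries were of muscle tissue, and markers of other cell types differed between the stages in expression. Whether an index changed within cells or with the mix of cells was not tested, here and for the bins, runs and classes of genes below. Over the bins of all placed genes the median index change was 0.812. Over all bins it was 0.178, and 0.0261 after quantile normalization. The anchor genes as a group did not pass the test against all placed genes (median 0.997, permutation p = 0.422 by the shifts). The bin of MYOG on chromosome 9 (113780001 to 113800000, Sscrofa11.1) went from an index of -1.47 ± 0.112 to 1.39 ± 0.0330 (SD, n = 3 per stage, adjusted p = 1.12e-05), although MYOG expression did not pass the test. MSTN on chromosome 15 (94620001 to 94640000) went from -0.721 ± 0.210 to 0.983 ± 0.160 (adjusted p = 6.51e-05), and SLN on chromosome 9 (36220001 to 36240000) from -0.222 ± 0.145 to 1.06 ± 0.487 (adjusted p = 0.00131). NEFL on chromosome 14 (8980001 to 9000000) went from 0.571 ± 0.260 to -2.20 ± 0.258 (adjusted p = 1.67e-05). MYH2, the fast 2A myosin, went from 0.269 ± 0.229 to -0.252 ± 0.281 on chromosome 12 (adjusted p = 0.0470), and its neighbour MYH1, another fast myosin, from -0.332 ± 0.262 to -0.880 ± 0.298 (adjusted p = 0.0454). MYF5 (-1.60 to -0.998) and MYF6 (-1.83 to -0.34) rose past the test and stayed below 0. PAX7 rose within A (2.63 to 3.74, adjusted p = 0.000542), a change that did not pass after quantile normalization of the index (adjusted p = 0.234).

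**Figure D4:**
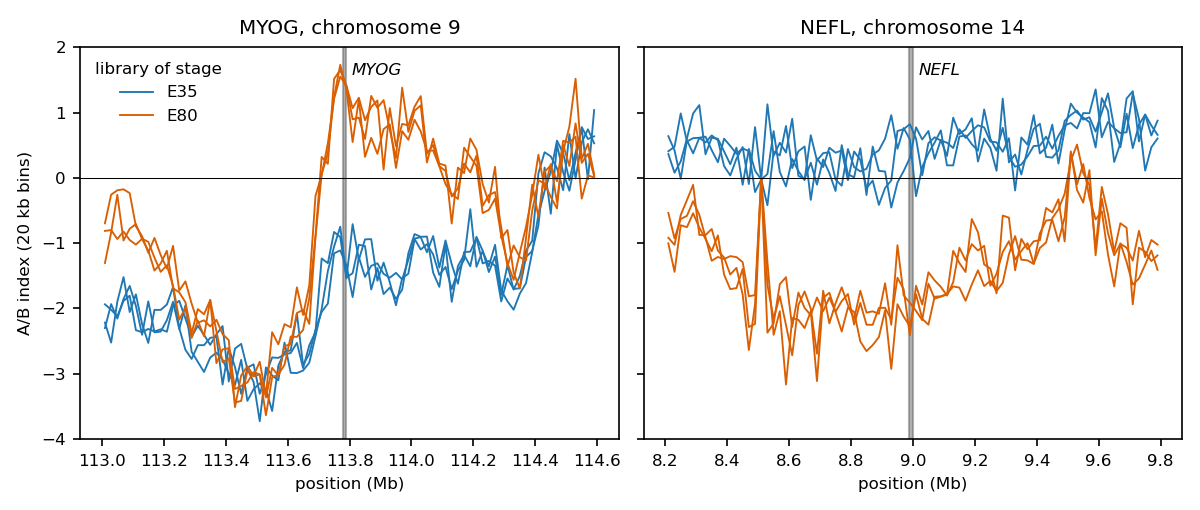
A/B index per 20 kb bin in the 6 Hi-C libraries around MYOG on chromosome 9 and around NEFL on chromosome 14, with positions in Mb and 1 line per library. Over the MYOG bin the E80 libraries lay above 0 and the E35 libraries below, and over the NEFL bin the order was the opposite.

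Genome-wide 73232 bins (64.6%) passed the limma test of the index, 42380 higher and 30852 lower at E80, and quantile normalization left 28008 higher and 25342 lower. Of the bins called higher 67.4% were in A at both stages, and of those called lower 76.4% were in B at both. The spread of the index was wider at E80 (SD 2.63 ± 0.116 against 2.06 ± 0.00807, exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allow). Changes of sign past the test numbered 4216 bins from A to B (3.72%, 84.3 Mb) and 7143 from B to A (6.31%, 143 Mb). The excess of B to A shrank under scaling, which gave 5305 and 5577 bins after quantile normalization and 5431 and 5678 after centring, and requiring the sign in all 3 libraries without a test gave 2763 and 4829. Index above 0 was read as A because those bins held 12.2 genes per Mb against 4.76 below 0 at E35, and 12.2 against 4.35 at E80. The sign hardly separated placed genes by expression at E35, with a median of 13.27 TPM above 0 and 12.05 TPM below. At E80 these medians were 11.79 and 4.60 TPM.

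The longest run from A to B covered 2120 kb of chromosome 7 (118000001 to 120120000) and held VRK1, a kinase of cell division, whose expression fell (-0.81). Another of 1880 kb on chromosome 6 (32120001 to 34000000) held SALL1 and TOX3, of which TOX3 fell (-1.50), and the third run, of 1200 kb on chromosome 6 (15840001 to 17040000), held ZFHX3, a transcription factor that fell (-2.24). The longest run from B to A covered 2500 kb of chromosome 1 (23340001 to 25840000), where TXLNB, a muscle taxilin, rose by 1.67, while ABRACL (-2.44), NHSL1 (-0.84) and REPS1 (-0.45) fell, and CITED2, HECA and CCDC28A did not pass. REPS1 did not pass under median-of-ratios scaling (adjusted p = 0.245). A neighbouring run of 1860 kb (25980001 to 27840000) held MAP3K5 (1.29) and ARFGEF3 (1.29), which rose, besides NHSL1, and TNFAIP3, IFNGR1, PEX7, PERP and MAP7, which did not pass, although TNFAIP3 and IFNGR1 did so upward under median-of-ratios scaling. The run of 1600 kb on chromosome 9 (117720001 to 119320000) held ASTN1, a neuronal adhesion protein, which fell (-2.23), and PAPPA2 and BRINP2, which did not pass.

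TADs of several anchor genes lost D-score, the deposited measure per TAD that lies between 0 and 1 and whose formula the files do not state. The TAD of NEFL on chromosome 14 (8520001 to 9100000) went from 0.333 ± 0.00291 to 0.308 ± 0.000428 (adjusted p = 1.47e-05), and that of DLK1 on chromosome 7 from 0.557 ± 0.00578 to 0.517 ± 0.00882 (adjusted p = 5.65e-05). That of MUSK went from 0.303 ± 0.00306 to 0.283 ± 0.00197 and that of MEF2D from 0.473 ± 0.00472 to 0.458 ± 0.00215. MATN2 lay in a TAD that rose (0.287 to 0.294, adjusted p = 0.0453). The D-scores around MYOG (0.237 to 0.228), PAX7, SLN, MYF5 and MYF6 fell as deposited but did not pass after centring each library on its median. Those around MYOD1, MSTN, SOX6 and IGF2BP1 did not pass as deposited and rose after centring. The largest falls were on chromosome 11 (64460001 to 64940000, 0.463 ± 0.0216 to 0.357 ± 0.00586), chromosome 9 (1440001 to 1920000, 0.402 to 0.311) and chromosome 14 (5900001 to 6160000, 0.453 to 0.372). The largest rises were on chromosome 9 (63220001 to 63420000, 0.0386 to 0.115), chromosome 6 (164520001 to 164700000, 0.454 to 0.512, with CYP4A21) and chromosome 14 (87300001 to 87440000, 0.125 to 0.175). None of these 6 TADs held a placed gene that was tested for expression.

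Of 3654 consensus TADs 2486 passed the limma test, 315 higher and 2171 lower (12.7% higher). After centring 1302 were higher and 1049 lower (55.4% higher) and after quantile normalization 1228 and 1096 (52.8% higher). The median D-score itself went from 0.280 ± 0.00269 to 0.271 ± 0.000737 (exact permutation p = 0.1, two-sided). The E80 libraries held fewer TADs, 3955 to 3971 against 4060 to 4086 (exact permutation p = 0.1, the smallest possible), with a median length of 440 kb against 460 kb. The mean length went the other way, 508 ± 0.619 kb against 503 ± 0.984 kb (SD, n = 3 per stage, exact permutation p = 0.1). In the lists per library TADs were thus neither shorter nor longer by both measures. The authors' merged list per stage held 4028 TADs at E80 against 4050 at E35. There the median was 440 kb against 460 kb and the mean 503.5 kb against 506.5 kb, so the mean was shorter at E80. Of TAD edges 94.4% lay within 40 kb of an edge of another library of the same stage and 85.5% within 40 kb of one of the other stage, a difference of 8.86 points (exact permutation p = 0.1). In all 3 libraries of E35 and none of E80, or the reverse, 424 and 427 edges were found, 851 together, against at most 35 in any other split of the libraries into 3 and 3.

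Relative to genes in bins that kept their sign, genes in bins from A to B fell and genes in bins from B to A rose, by small amounts. The 137 tested genes in bins that went from A to B had a median log2 change of -0.51 against -0.30 for 9387 genes in bins that kept their sign, a difference of -0.21. Past the test 4 of them were higher and 69 lower. The 830 genes in bins from B to A had a median of -0.20, a difference of 0.10, with 115 higher and 259 lower, so that most of those past the test fell with TPM as deposited. Under median-of-ratios scaling 210 of them were higher and 102 lower (median 0.10, difference 0.11), and of the genes from A to B 11 were higher and 43 lower (difference -0.21). Without E35 replicate 1 the difference for B to A was 0.0574, and without a filter on low values 0.0558 (permutation p = 0.00699 and 0.00899). Both differences had a permutation p = 0.0001 by 10000 circular shifts of the gene order, the smallest the shifts can give (adjusted p = 0.000122 over 11 such tests). Across 10440 genes, which are not independent replicates, the change of index and of expression had Pearson r = 0.177 and Spearman rho = 0.139 (each p = 0.0001, the smallest the shifts can give, adjusted p = 0.000122). Without that filter the difference for A to B was -0.0375 and did not pass (permutation p = 0.317). Genes in 24 fixed lists that lay in bins from B to A included MYOG, MSTN and MEF2C among myogenic regulators, MYL1 and MYPN of the sarcomere, and SLN, JPH1, CACNA2D1 and ASPH of calcium handling. Of 3 switched neuron markers NEFL and STMN4 went from A to B and GAP43 from B to A. None of the 24 lists passed a shift test of its index change (adjusted p = 0.857 for the myogenic, sarcomere and calcium lists and 0.163 for neurons).

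Genes in TADs whose D-score rose had a median change of -0.18 (n = 692) and those in TADs whose D-score fell one of -0.34 (n = 5035), against -0.23 for 2826 genes in TADs that did not pass. The first difference, 0.06, had a permutation p = 0.0188 by the shifts (adjusted p = 0.0207). In the same permutation test it was lost without E35 replicate 1 (difference 0.0355, p = 0.174), without E80 replicate 1 (0.0424, p = 0.0749) and without a filter on low values (0.0422, p = 0.0719). The second, -0.10, had a permutation p = 0.0001, the smallest the shifts can give (adjusted p = 0.000122). With D-scores centred on each library median the classes held 2945 and 2670 genes, with differences of 0.0845 and -0.0406 (permutation p = 0.000999, the smallest that 1000 shifts can give, and 0.00599). Over 8553 genes Pearson r was 0.109 and Spearman rho 0.117 (each p = 0.0001, adjusted p = 0.000122).

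**Figure D5:**
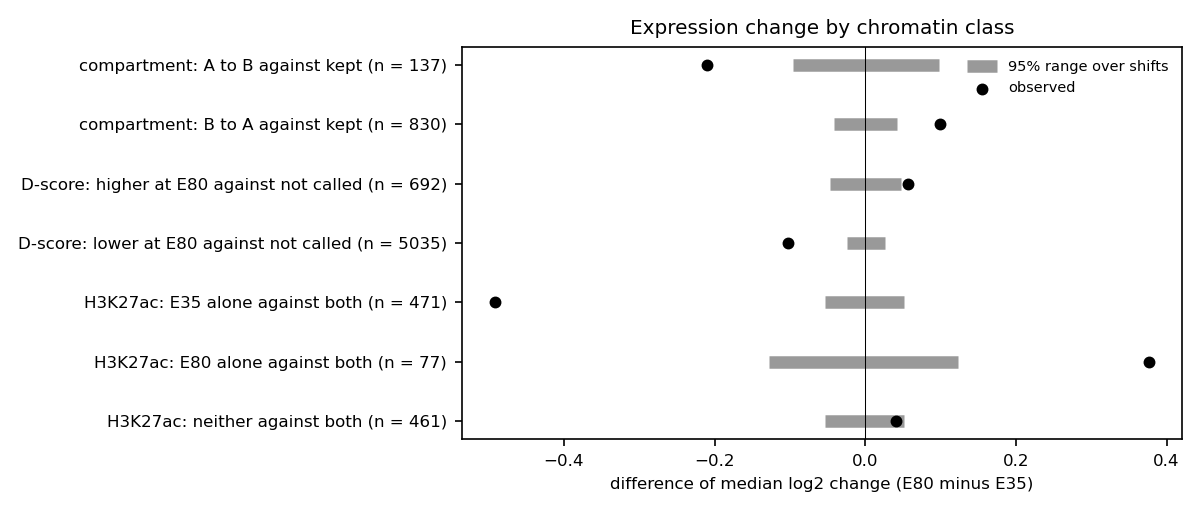
Difference of the median log2 expression change between each class of genes and its reference class (points), with the range that holds 95% of the differences over circular shifts of the gene order (bars). The classes of genes from A to B (-0.21) and with gene-end H3K27ac at E35 alone (-0.49) lay below their ranges, and that with H3K27ac at E80 alone (0.38) above.

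H3K27ac marked the ends of the anchor genes with a known position in all 3 libraries, except those of MYH2, which lacked a region in E35 replicate 2, and of NEFL, which were marked at E35 alone. NEFL had a region in both E35 libraries (highest fold over input 2.35 and 2.17) and none at E80. The longest regions with no overlap at the other stage lay at E35 in CDH4, a cadherin (chromosome 17, 61323001 to 61377600), in NRP2, a receptor of semaphorins (chromosome 15, 109019401 to 109072400), and between genes on chromosome 14 (141030401 to 141077200). At E80 they lay in ARHGAP18 (chromosome 1, 33591801 to 33615400), in MLIP, a protein of muscle lamina (chromosome 7, 26747001 to 26766000), and between genes on chromosome 8 (76286601 to 76304200). MLIP rose from 1.68 ± 0.693 to 45.2 ± 7.04 TPM (log2 change 4.13), ARHGAP18 rose by 1.48, NRP2 fell (-1.14), and CDH4 did not pass (-0.38, adjusted p = 0.236).

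The lists held 62547 and 64341 regions at E35 and 42976 at E80 on the assembled chromosomes, covering 343, 393 and 242 Mb, with a median fold over input of 2.1, 1.98 and 1.68. The ChIP reads in the regions numbered 24176942, 29481731 and 20740103. Of the E80 regions 80.3% overlapped an E35 region found in both libraries, against a mean of 25.9% over 100 shifts of their positions. Of the 45136 E35 regions 60.6% overlapped one at E80. Between the E35 libraries 89.0% of the replicate 1 regions overlapped replicate 2, and 80.9% of the replicate 2 regions overlapped replicate 1. Of the E80 regions 81.7% overlapped E35 replicate 1 alone and 83.4% replicate 2 alone, a share like that between the E35 libraries. In the other direction 53.9% and 50.9% of the regions of these E35 libraries overlapped E80. With 1 library at E80 no test between the stages was made, and a region missing from its list, which was shorter and weaker, is not shown to be absent. The labels also give a different antibody code for each H3K27ac library, so a difference between antibodies cannot be separated from 1 between stages in the overlaps or in the classes of genes marked at 1 stage alone.

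Among genes with an H3K27ac region at a gene end at E35 alone were STMN2, SFRP1 and CYTL1, which fell, and MBP, which rose. This class had a median log2 change of -0.78 (n = 471), against -0.29 for 9815 genes with a region at both stages. The difference was -0.49, with 30 higher and 241 lower. Genes with one at E80 alone, among them EGF and RGS5, had a median of 0.09 (n = 77), a difference of 0.38, with 25 higher and 16 lower. With gene ends within 5 kb the latter difference was 0.215, with 15 higher and 18 lower. At an FDR of at most 1e-10 it was 0.817 (n = 69), with 32 higher and 10 lower, and that for E35 alone was -0.274 (n = 976), with 92 higher and 442 lower. With regions as deposited and ends within 2 kb, the differences of -0.49 and 0.38 each had a permutation p = 0.0001, the smallest the shifts can give (adjusted p = 0.000122). The 461 genes with no region at either stage differed by 0.04 and did not pass (adjusted p = 0.123). Without a filter on low values the difference of medians for E35 alone was reversed (0.0514, permutation p = 0.00400), in a class that then held 1054 genes. Past the test 44 of them were higher and 275 lower, against 972 and 3446 of the genes marked at both stages. Leaving out any 1 RNA-seq library took the difference for genes with no region to between 0.0557 and 0.0947 and past an unadjusted p of 0.05.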

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

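The tests of a single library, of nerve with glia, and those of HOX genes were chosen only after the result was seen. The test of the highest genes, that of region lists of 1 length and the splits of the libraries were written before.

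H3K27ac regions also lay on unplaced scaffolds, which no comparison used. They numbered 1095 and 1085 in E35 replicates 1 and 2 and 1233 in the E80 library, and held 3.83%, 3.65% and 8.63% of the ChIP reads in regions. They were singled out because they are a signal outside the chromosomes compared, and no control library was called in the same way.

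With TPM as deposited more genes were lower than higher at E80. The 100 genes of highest mean TPM held 32.3% ± 1.01 of TPM at E35 and 41.7% ± 3.76 at E80 (SD, n = 3). When they were left out and the libraries rescaled to 1 total, the median log2 change was -0.0437 over 15044 genes. Before, it was -0.30 over 14353 genes. The rescaling also made the library totals equal, which had averaged 834800 TPM at E35 and 797100 TPM at E80. Without E35 replicate 3 or E80 replicate 2 the median nearest 0 was -0.2628, which argues against a single one of these libraries. The excess of lower genes may therefore largely come from the share of TPM taken by the highest genes, and in part from the library totals. Both the share and the totals differed between the stages. Whether the total RNA per cell differed stays open.

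Most neuron markers had an H3K27ac region at their ends in both E35 libraries and none in the single E80 library, which does not show that the mark was absent. Of 10 placed neuron markers 8 had it at E35 alone (GAP43, MAP2, NEFL, PRPH, SNAP25, STMN2, STMN4 and SYT1), against 4.35% of all genes, and 10000 random sets gave at most 4. With lists of 1 length ranked by fold the number was 7, which argues against the shorter E80 list as the whole cause. The Schwann and glia list lay 0.5198 above the median of all genes (SD of its members 1.08) and the neuron list at -1.59 (SD 1.72), which argues against less nerve with its glia, although the glia list lost its call without E35 replicate 3 (adjusted p = 0.0611) or among genes of at least 5 TPM (0.102). A loss of neural tissue around the early muscle, or of neuronal transcripts in other cells, could each give this pattern, and with 1 ChIP library at E80, labelled with another antibody code than those at E35, both stay open, as does the antibody.

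HOX genes differed between the E35 libraries. Over 25 HOX genes the difference of E35 replicate 1 from the other replicates fell with paralog number (Spearman rho = -0.7953), and that of E35 replicate 2 rose with it (0.777), which is consistent with samples taken at different levels of the body axis. Their median SD on the log2 scale over the E35 libraries was 1.453, against a 99th percentile of 0.340 in random sets of like TPM, which argues against the spread of weakly expressed genes. The labels give no level of the body axis, so a sample of other tissue, animal or label stays open.

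With 3 libraries against 3 there are 10 splits, so the share of splits with a result as large, here 1 of 10 for each table, cannot fall under 0.1. The real split gave 6615 genes, 73232 bins and 2486 TADs by limma, and the highest other split gave 0 for each. At an unadjusted p under 0.05 the real split gave 7849, 77363 and 2586, and the highest other 250, 700 and 41.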

How the results depend on the processing

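The settings chosen only after the result was seen were TPM rescaled without 2 genes, an FDR of at most 0.01 with a fold over 1, the quantile-normalized index for expression, median-of-ratios scaling for expression by D-score, and leaving out an E35 H3K27ac library. For all moved values below, the cause was not tested.

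Scaling moved the balance of directions. Genes called higher and lower were 2542 and 2402 under median-of-ratios scaling and 2473 and 2574 under quantile normalization, and 3243 were lower with TPM rescaled without the 2 leading genes. Quantile normalization left 28008 bins with a higher index and gave 1228 TADs higher and 1096 lower in D-score, and centring gave 1302 and 1049. Requiring an absolute log2 change of at least 1 left 2285 genes, 729 higher and 1556 lower, by construction. The rule of 1 sign in all 3 libraries gave 2763 bins from A to B.

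With an estimated correlation 0 of the 14 lists passed camera of limma (3 of 24 at an unadjusted p under 0.05, while fry called 14). Without a filter on low values the difference for genes from A to B was -0.0375 (permutation p = 0.317), that for a raised D-score 0.0422 (p = 0.0719), and that for H3K27ac at E35 alone reversed to 0.0514 (p = 0.00400). In this last class 44 genes were higher and 275 lower past the test, against 972 and 3446 of those marked at both stages.

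Genes with no H3K27ac at their ends differed from those marked at both stages by 0.196 without a filter, 0.0708 with ends within 5 kb, 0.0967 with E35 regions of either library, 0.0663 at an FDR of at most 1e-10, and a reversed -0.0059 under median-of-ratios scaling (permutation p = 0.821).

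The share of E80 regions that overlapped E35, and of E35 regions that overlapped E80, was 82.2% and 54.6% at an FDR of at most 1e-10, 75.3% and 40.2% with an overlap of 50%, 86.2% and 48.3% with either library, 67.3% and 72.2% with lists of the same number, and 81.6% and 58.0% at an FDR of at most 0.01 with a fold over 1.

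Leaving out each library in turn gave 938 to 1441 genes higher, the least without E80 replicate 3, and differences of 0.0355 to 0.0756 for a raised D-score, lost without E35 replicate 1 (permutation p = 0.174) or E80 replicate 1 (0.0749). It gave 0.0557 to 0.0947 for genes with no H3K27ac, and 81.7% to 83.4% and 50.9% to 53.9% for the region overlaps. Of 57 named genes past the test 49 kept their call under all 14 alternatives and 8 lost it under at least 1.

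The labels do not say whether the replicate numbers pair the libraries. Between libraries of 1 number the deviations from the stage mean correlated at -0.01, -0.09 and -0.09 for expression, -0.05, -0.02 and 0.00 for the index, and 0.17, -0.02 and 0.10 for the D-score. Of 6 libraries 0, 0 and 3 had their highest correlation across stages with their own number for expression, index and D-score, so for the D-score a pairing stays open. With the number as a block 5390 genes, 71330 bins and 2608 TADs passed, and 14 lists.

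Placing genes by their transcription start was not run, since no strand was given, and the middle of the gene body was used. For Hi-C, autosomes alone moved nothing, since its bins and consensus TADs lie on 18 autosomes. Expression and H3K27ac also covered X, and no comparison on autosomes alone is given for them. Depth could not be varied, as these tables carry no counts for expression or Hi-C.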

Other observations

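The comparison of fixed lists with compartments and the values per library given here were chosen only after the result was seen.

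Of 17 fibre type regulators 5 lay in bins that went from B to A (PPARGC1A, ESRRG, FNIP1, NR4A3 and PROX1), but the index change of that list did not pass (median 0.879 against 0.812 for all genes, permutation p = 0.743, adjusted p = 0.939). Also in such bins lay PDK4, ACADL and ETFDH of the fatty acid list and PKM, UGP2 and FBP2 of glycolysis. Chromatin genes there were EZH2, RAD21 and SMC4, although that list fell in expression, and of the matrix COL5A2 and POSTN. Of 10440 placed genes 830 (7.95%) lay in such bins and 137 (1.31%) in bins from A to B. The neuron list had a median index change of -0.05 against 0.81 for all genes, with a permutation p = 0.0068 by the shifts but an adjusted p = 0.163 over the lists, so it did not pass.

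An identifier without a symbol, ENSSSCG00000032395, took 12.57% of the TPM of E80 replicate 2, at 98438 TPM, against 26725 and 31700 TPM in the other E80 libraries. ENSSSCG00000032599 took another 5.93% there.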
